A study of Homo sapiens with 24 samples.

How the data were processed

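RNA of RKO cells, an established human colorectal carcinoma line, was measured on 24 Affymetrix HG-U133 Plus 2.0 arrays. Per the labels, cells were given the methanol vehicle or 5, 20 or 60 µM 4-hydroxy-2-nonenal (HNE) for 6 or 24 h, with 3 arrays in each of 8 groups, named here by dose, time and replicate number. The authors deposited a linear intensity for each of 54675 probe sets and array, from 0.1 to 40285.7, with 0 missing values and no detection calls. In every array the mean intensity after trimming 2% at each end was 500 to 500.1, so the deposited intensity had already been scaled to a common mean, and it was used without further scaling. The software behind those values is not given in the sources used here.

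All arrays were checked for repeated columns, and 0 of 276 pairs had most of their values identical. Pearson correlations of log2 intensity lay between 0.939 and 0.963 within groups and between 0.918 and 0.971 between groups. A pseudocount of 16 was added before taking log2. The 62 control probe sets were left out, 41097 probe sets named a single gene symbol, 1801 named several and 11777 named none. A probe set was kept when it lay above the median (the 50th percentile) of its array in at least 3 arrays, which 32836 did. For each gene the probe set with a single symbol and the highest mean was used, which gave 14256 genes.

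Group means of all 24 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a variance trend), with 16 residual and 6.75 prior degrees of freedom. Each dose was compared with the vehicle of its time, 60 µM with 20 µM at each time, vehicle at 24 h with vehicle at 6 h, and the difference between the times was tested as an interaction for 20 and 60 µM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its comparison. Errors given with log2 folds are limma's standard errors, and a fold is the log2 fold taken out of the log. In comparisons of 2 groups, intensities are given in place of a fold where a group mean of a named gene lay under 59.4, the highest lower quartile of any array. Interactions of such genes are given with their values at other pseudocounts. Groups are too small for a rank test, since an exact two-sided permutation test of 3 arrays against 3 cannot give a p under 0.1.

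Each list of genes was fixed, like the comparisons, the rule for named genes and most of the alternatives, before the data were examined. The 20 lists were NRF2 targets, HSF1 heat shock genes, ER chaperones and ERAD, ATF4 amino acid response, metallothioneins, p53 targets, NF-kB inflammatory targets, immediate early genes, G2/M and mitosis, DNA replication and G1/S, cholesterol synthesis, proteasome subunits, aldehyde metabolism, ribosome biogenesis, hypoxia and glycolysis, interferon response, apoptosis regulators, oxidative phosphorylation, colon epithelium markers, and markers of other cell types (fibroblast, endothelial and blood). They held 398 distinct genes, of which 38 had no probe set naming them alone and 31 lay below the signal filter. The NRF2 and aldehyde lists shared 5 genes, the p53 and apoptosis lists 4, and 7 other pairs of lists 1 each. Lists were tested with limma's camera with its preset correlation of 0.01, adjusted over 220 tests (20 lists in 11 comparisons), and again with an estimated correlation. The limma test fry was run too, but its values are not given here and no statement rests on them. Members were also adjusted over the list alone.

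Named genes were those with the largest change among called genes whose 3 treated arrays all lay beyond all 3 arrays of the other group: 12 higher and 10 lower at 60 µM at each time, 6 and 6 at 20 µM, 3 and 3 at 5 µM, and 5 and 5 for 60 against 20 µM and for the vehicle times. The interactions took 5 and 5 without that condition. Up to 4 called members per list, those with the smallest p, could be named besides. Where such a gene lost its call in another setting it is counted and not named in the report, except where few genes were called. The closing section names it where it lists differences between the times or changes of direction, a choice made after the alternatives had been computed. A gene that a setting did not test was not counted as losing its call there.

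The alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 75th percentile, pseudocounts of 1 and 64, no variance trend, the mean of a gene's probe sets, all probe sets apart, only the arrays of the same time, only the groups compared, the replicate number as a block, that block within each time, leaving out each array in turn, and a fold of at least 2 besides the adjusted p. Adding the 3′ to 5′ differences of the GAPDH and ACTB control probe sets as covariates was chosen after seeing the data. Replicate numbers were taken to pair the arrays of a comparison only where every pair of arrays with equal numbers correlated above 0.1 in their deviations from the group means. That held for 60 µM at 6 h, for each dose at 24 h, for the interaction of 60 µM and for the vehicle times. All 24 arrays nevertheless correlated most, on average, with arrays of their own number. Counts that moved with the block are given in the section on processing, also for the other comparisons. The tests were also run on simulated data, with the gene means and pooled spread of all 24 arrays and noise independent between genes. Of genes given a log2 change of 1 in the group standing for 60 µM at 6 h, 68.7% of 67 were called. Of the unchanged genes among 14256, 10 were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.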

Results

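The 24 arrays measured RNA levels in RKO cells, a human colorectal carcinoma line, after 6 or 24 h with the methanol vehicle or with 5, 20 or 60 µM HNE, a reactive aldehyde formed when membrane lipids are oxidised. Each of the 8 groups held 3 arrays, which limits the precision of every value. The median intensity of an array lay between 137.1 and 191.3. Replicate 2 of 60 µM at 24 h had the highest median and the lowest mean correlation with the other arrays, 0.931. The labels do not say whether replicates were separate cultures, so each p measures the spread between these samples, which may be technical. For the 3′ to 5′ differences of GAPDH and ACTB, a measure of RNA quality, an exact permutation test of 3 arrays against 3 decides nothing, since its smallest p (two-sided, n = 3) is 0.1. That of GAPDH at 20 µM and 6 h reached it (-0.131 ± 0.039 against -0.091 ± 0.011 in vehicle, SD, adjusted p = 1).

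**Figure D1:**
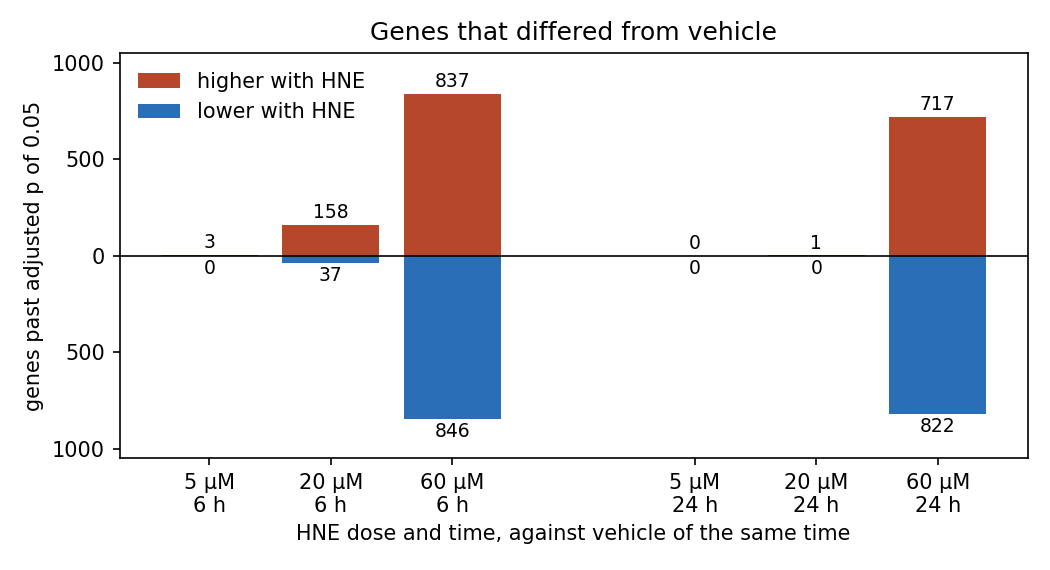
Bars give the number of genes with an adjusted p under 0.05 for each dose of HNE (µM) against the vehicle of the same time, higher above 0 and lower below 0, at 6 h and 24 h. Of 14256 genes, 3, 195 and 1683 were called at 6 h and 0, 1 and 1539 at 24 h with rising dose.

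At 5 µM and 6 h the clearest change was in HMOX1, the heme oxygenase that breaks down heme. Its intensity was 8592 ± 2917 against 2283 ± 558.3 in vehicle (SD, n = 3), which is 3.69-fold higher (log2 1.88 ± 0.24, adjusted p = 0.00129). SLC16A14, a member of the monocarboxylate transporter family, was 1.71-fold higher (log2 0.77 ± 0.11, adjusted p = 0.00491). TXNRD1, the cytosolic thioredoxin reductase, was 1.54-fold higher (log2 0.62 ± 0.10, adjusted p = 0.0181). Of the NRF2 targets, genes of the antioxidant and electrophile response, 2 of 24 measured rose and 22 did not pass, while 5 rose when adjusted over the list alone. The list as a whole lay higher, with 20 of 24 members above 0 and an adjusted p of 9.05e-13 (0.00314 with an estimated correlation). Its median log2 fold was 0.22, and 0.14 without vehicle 6 h replicate 2. Another 1 of the 20 lists passed but lost its call in other settings, and had adjusted p = 0.515 with an estimated correlation. Only 3 genes were called in all, each higher, and 412 had an unadjusted p under 0.05 where chance gives 713. The errors of the fit include the spread between replicate numbers, which can lower such counts, so 412 does not show that nothing else changed. With the replicate number as a block more genes were called, as the section on processing gives. With each array centred on its median 3 were called, 2 of them higher. SLC16A14 lost its call without 5 µM 6 h replicate 1 (adjusted p = 0.06, with 0.00156 to 0.139 over all alternatives), 5 µM 6 h replicate 3 (0.0552) or vehicle 6 h replicate 3 (0.0699). TXNRD1 lost it without any of the 6 arrays, with adjusted p of 0.00186 to 0.178 over all alternatives: 0.0786, 0.0912 and 0.178 without 5 µM 6 h replicates 1, 2 and 3, and 0.0761, 0.152 and 0.0728 without vehicle 6 h replicates 1, 2 and 3.

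At 20 µM and 6 h HMOX1 was 8.05-fold higher than in vehicle (log2 3.01 ± 0.24, adjusted p = 2.26e-07, n = 3). SLC7A11, the cystine transporter subunit that supplies glutathione synthesis, was 6.48-fold higher (log2 2.70 ± 0.34). CCN2, a secreted matricellular protein, was 4.97-fold higher (log2 2.31 ± 0.28). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 4.66-fold lower (log2 -2.22 ± 0.29), and RHOF, a small GTPase, was 2.62-fold lower (log2 -1.39 ± 0.19). Another 3 higher and 4 lower genes named by the rule lost their call in at least 1 other setting.

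NRF2 targets led the lists at that dose: 9 of 24 rose, 1 fell and 14 did not pass (14 rose and 1 fell adjusted over the list alone), with a median log2 fold of 0.45. Its adjusted p was 1.65e-15 (0.00174 with an estimated correlation). Beside HMOX1 and SLC7A11, GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, rose by 1.36 ± 0.17 and TXNRD1 by 0.81 ± 0.10 on the log2 scale. Ribosome biogenesis genes, which build ribosomes, lay lower as a list (median -0.22, adjusted p = 5.5e-05, 0.0266 with an estimated correlation). Of its 15 members 1 fell, or 2 adjusted over the list alone. NF-kB inflammatory targets also lay lower (median -0.37, adjusted p = 0.000399, but adjusted p = 0.131 with an estimated correlation). Of those 0 of 14 were called, and 2 fell adjusted over the list alone. Cholesterol synthesis genes lay higher (median 0.19, adjusted p = 0.000747, but adjusted p = 0.266 with an estimated correlation). Of those 1 of 17 rose, or 4 adjusted over the list alone. Another 6 lists passed the preset correlation but not every other setting, with adjusted p between 0.106 and 0.67 with an estimated correlation. Single members of other lists that rose were HSPA4L, a chaperone of the HSP110 family (log2 0.93 ± 0.12), TP53I3, a p53-induced oxidoreductase (0.78 ± 0.12), and ADM, the peptide hormone adrenomedullin (0.90 ± 0.17). In all, 195 genes were called, 158 higher and 37 lower. That count fell to 108, 111 and 104 without 20 µM 6 h replicates 1, 2 and 3, to 85 and 97 without vehicle 6 h replicates 1 and 2, and was 95 with each array centred on its median. It rose with the replicate number as a block, as the section on processing gives.

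**Figure D2:**
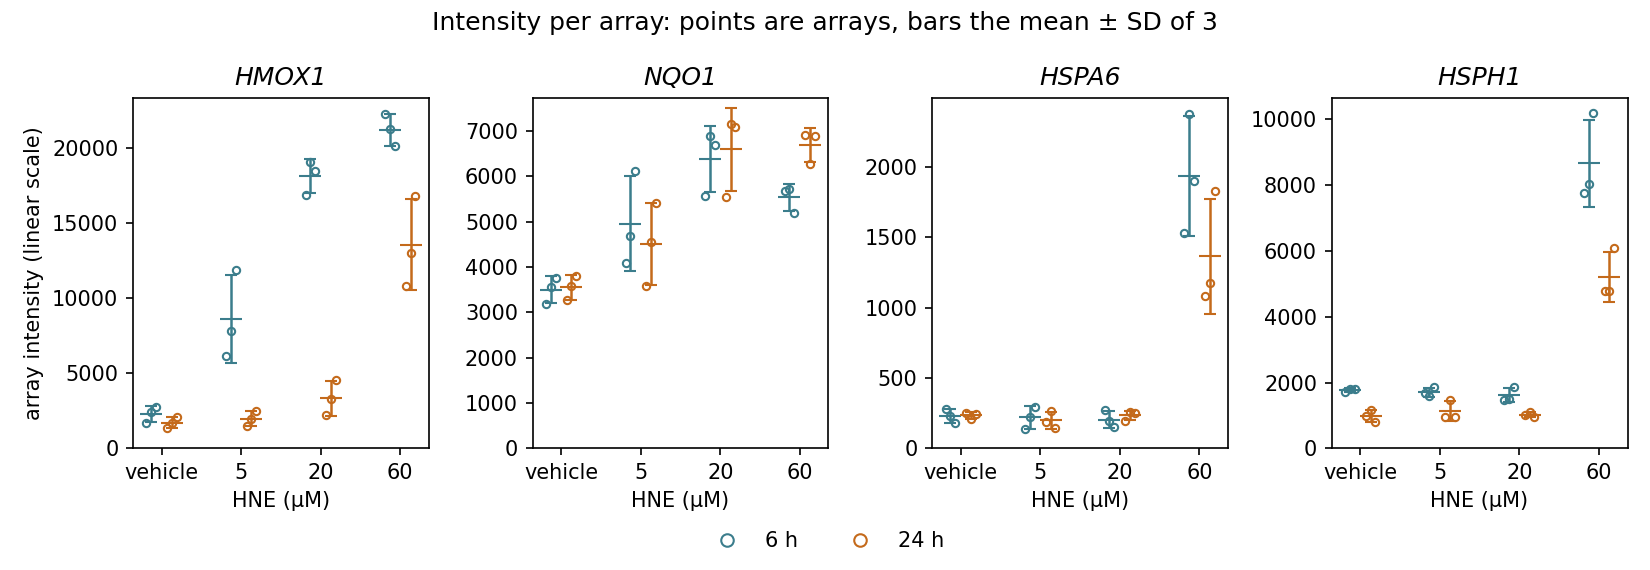
Intensity (linear, arbitrary units) of HMOX1 and NQO1, both NRF2 targets, and of HSPA6 and HSPH1, both heat shock genes, by dose of HNE (µM) at 6 h and 24 h, where points are arrays and bars the mean ± SD of 3. HMOX1 averaged 2283, 8592, 18130 and 21190 with rising dose at 6 h, while HSPH1 averaged 1770, 1709, 1616 and 8659.

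At 60 µM and 6 h the largest rise was in ZFAND2A, a proteasome-associated zinc finger protein induced by arsenite, 17.6-fold higher than in vehicle (log2 4.14 ± 0.22, adjusted p = 3.07e-11, n = 3). Chaperone genes rose too: the inducible HSP70 gene HSPA6 was 7.89-fold higher (log2 2.98 ± 0.27) and the cochaperone DNAJB4 5.84-fold higher (2.54 ± 0.25). HMOX1 was 9.42-fold higher (log2 3.23 ± 0.24) and SLC7A11 5.09-fold higher (2.35 ± 0.34). Single genes outside these were higher too: the transcriptional inhibitor EID3 8.89-fold, the stress sensor GADD45B 5.84-fold, FOSB, an AP-1 subunit, 5.51-fold, and the stress-induced gene SESN2 5.47-fold. ACTRT3, an actin-related protein, was 8.93-fold higher. RGS20, a regulator of G protein signalling, and the pseudogene RRN3P2 rose from dim signals of 33.73 ± 17.18 and 38.1 ± 19.2 in vehicle to 439.8 ± 44.94 and 417.2 ± 57.72 (SD, n = 3). No fold is given for these 2, since it would depend on the pseudocount.

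Among genes lower at 60 µM and 6 h, MAT2A, which makes S-adenosylmethionine, was 3.17-fold lower (log2 -1.67 ± 0.13). RRS1, a factor of ribosome assembly, was 3.03-fold lower (-1.60 ± 0.14), and SCO2, a copper chaperone of cytochrome c oxidase, 3.09-fold lower (-1.63 ± 0.19). FBXO5, an inhibitor of the anaphase-promoting complex, was 3.04-fold lower (-1.61 ± 0.23), the zinc finger gene ZNF574 4.17-fold lower (-2.06 ± 0.44), and the lysosomal acetyltransferase HGSNAT 2.96-fold lower (-1.57 ± 0.25). Another 4 lower genes named by the rule lost their call in other settings. In all, 1683 genes were called, 837 higher and 846 lower. With each array centred on its median 1433 were called, 431 of them higher.

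HSF1 heat shock genes rose most uniformly at 60 µM and 6 h: 17 of 19 rose and 2 did not pass (all 19 rose adjusted over the list alone). The median log2 fold was 0.82 and the adjusted p 1.27e-19 (0.00687 with an estimated correlation). HSPH1, an HSP110 chaperone, rose by 2.27 ± 0.16 and HSPA4L by 1.49 ± 0.12 on the log2 scale. Of the NRF2 targets 12 of 24 rose, 1 fell and 11 did not pass (13 rose and 1 fell adjusted over the list alone). That list's adjusted p was 3.56e-09 (0.00687 with an estimated correlation). Of the ATF4 amino acid response genes 14 of 25 rose, 1 fell and 10 did not pass (19 and 1 adjusted over the list alone). Their median was 0.80 and the adjusted p 6.95e-13, but adjusted p = 0.117 with an estimated correlation. ATF3, a stress-induced transcription factor, rose by 2.33 ± 0.22, DDIT3, the transcription factor CHOP, by 2.01 ± 0.22, and PPP1R15A, a phosphatase subunit acting on eIF2α, by 1.84 ± 0.20. ER chaperones and ERAD genes followed with 8 of 18 higher and 10 not passing (9 adjusted over the list alone), among them HERPUD1 (2.33 ± 0.26) and DNAJB9 (1.00 ± 0.13), both of ER-associated degradation. That list had an adjusted p of 3.34e-05, and adjusted p = 0.148 with an estimated correlation. Of the cholesterol synthesis genes 8 of 17 rose and 9 did not pass (8 adjusted over the list alone). The adjusted p was 1.45e-06, but adjusted p = 0.104 with an estimated correlation. INSIG1, which holds sterol regulators in the ER, rose by 1.59 ± 0.15, and the enzymes HMGCS1, IDI1 and MSMO1 by 1.25 ± 0.17, 0.90 ± 0.13 and 0.83 ± 0.12.

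Genes of cell division and ribosome assembly lay lower at 60 µM and 6 h. Of the G2/M and mitosis genes 12 of 22 fell and 10 did not pass (14 fell adjusted over the list alone). The median was -0.41 and the adjusted p 4.36e-11 (0.0362 with an estimated correlation). Examples are the topoisomerase TOP2A (-0.83 ± 0.10), the cyclins CCNB1 (-0.79 ± 0.11) and CCNA2 (-0.79 ± 0.14), and the mitotic kinase PLK1 (-1.08 ± 0.19). Ribosome biogenesis genes fell in 7 of 15 cases, with 8 not passing (10 fell and 1 rose adjusted over the list alone). Their median was -0.47 and the adjusted p 5.13e-06 (0.015 with an estimated correlation). POLR1B, a subunit of RNA polymerase I, fell by 0.86 ± 0.11, and the nucleolar factor WDR43 fell by 0.83 ± 0.15.

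Another 5 lists passed in the main setting at 60 µM and 6 h but lost the call in others. Of the immediate early genes 5 of 15 rose and 2 fell (5 and 3 adjusted over the list alone). That list's adjusted p was 0.0124, 0.0634 without 60 µM 6 h replicate 1 and 0.00183 to 0.0634 over all alternatives, and adjusted p = 0.291 with an estimated correlation. Proteasome subunits rose in 5 of 25 cases (5 adjusted over the list alone). The adjusted p was 0.00458 and 0.000732 to 0.165 over all alternatives, with the highest under quantile normalization, and adjusted p = 0.36 with an estimated correlation. Oxidative phosphorylation genes rose in 1 of 20 cases (1 adjusted over the list alone). Their adjusted p was 0.00707 and 0.00126 to 0.165 over all alternatives, and adjusted p = 0.394 with an estimated correlation. Hypoxia and glycolysis genes rose in 4 and fell in 1 of 15 cases (4 and 1 adjusted over the list alone), among them ADM (1.88 ± 0.17) and the growth factor VEGFA (0.99 ± 0.19), both higher. The median of 0.13 turned to -0.06 under quantile normalization, and 60 µM 6 h replicate 1 left out gave 0.08. The adjusted p was 0.0264 and 0.0126 to 0.146 over all alternatives, and adjusted p = 0.106 with an estimated correlation. DNA replication and G1/S genes fell in 2 of 25 cases (2 adjusted over the list alone). Their adjusted p was 0.0124 and 0.00174 to 0.0845 over all alternatives, the highest with the stricter filter, and adjusted p = 0.523 with an estimated correlation.

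The remaining 8 lists did not pass at 60 µM and 6 h. NF-kB inflammatory targets fell in 3 of 14 cases, among them the adhesion molecule ICAM1 (-0.76 ± 0.15) and IER3 (-1.11 ± 0.26), both lower. That list's adjusted p was 0.0577, 0.0326 with the replicate number as a block, 0.0271 without 60 µM 6 h replicate 1, 0.0246 without vehicle 6 h replicate 3, and 0.0246 to 0.159 over all alternatives. Of 8 metallothionein genes 1 rose and 2 fell (adjusted p = 0.366, 0.000844 under quantile normalization and up to 0.58 over all alternatives). The mean of that list, 0.02, differed in sign from its median and test. Aldehyde metabolism genes rose in 2 and fell in 1 of 13 cases (adjusted p = 0.396), with CBR1, a carbonyl reductase, higher by 0.68 ± 0.12. Of 20 p53 targets 2 rose (adjusted p = 0.183, 0.0361 without vehicle 6 h replicate 3 and up to 0.496 over all alternatives). Of 19 apoptosis regulators 4 rose (adjusted p = 0.459), among them PMAIP1, a BH3-only protein (0.98 ± 0.16). Of 12 interferon response genes 1 rose (adjusted p = 0.188). Colon epithelium markers (0 of 5 called, adjusted p = 0.78) and markers of other cell types (0 of 8 called, adjusted p = 0.995) showed no call.

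**Figure D3:**
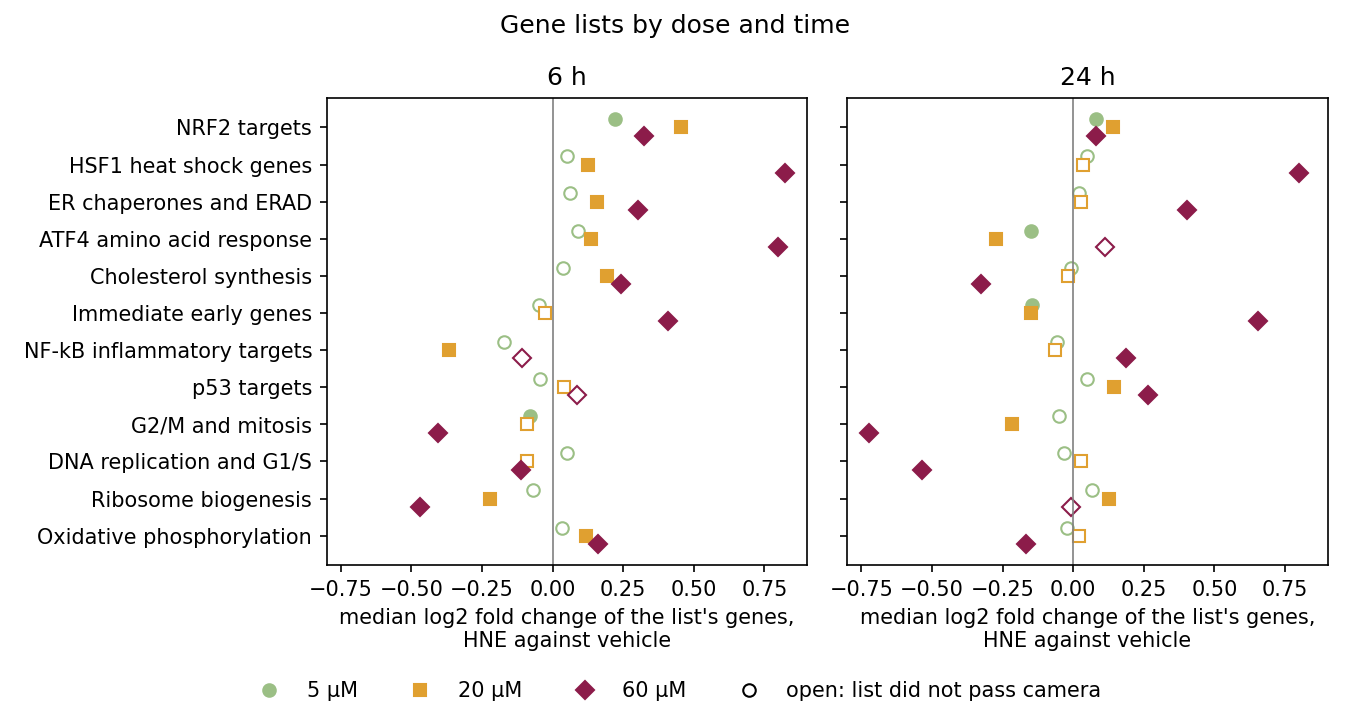
Median log2 fold against vehicle of 12 gene lists at 5, 20 and 60 µM HNE, at 6 h and at 24 h, where filled points passed camera with its preset correlation at an adjusted p under 0.05 and open points did not. At 60 µM the heat shock median was 0.82 at 6 h and 0.80 at 24 h, and the G2/M median was -0.41 and -0.72.

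Between 20 and 60 µM at 6 h the heat shock genes parted from the NRF2 targets. HSPA6 was 8.92-fold higher at 60 µM than at 20 µM (log2 3.16 ± 0.27, n = 3), ZFAND2A 8.63-fold, FOSB 13.3-fold and ACTRT3 6.21-fold, while FBXO5 was 3.38-fold and ZNF574 4.57-fold lower. Of the heat shock genes 12 of 19 were higher at 60 µM (14 adjusted over the list alone; adjusted p = 2.01e-18, 0.00687 with an estimated correlation), with HSPH1 higher by 2.41 ± 0.16 and the cochaperone DNAJB1 by 1.62 ± 0.17. Of the NRF2 targets only SRXN1, which repairs peroxiredoxins, was higher (0.60 ± 0.10), and 23 of 24 did not pass, with 1 higher adjusted over the list alone. The median of that list was 0.01 (-0.09 under quantile normalization and -0.11 with arrays centred) and its adjusted p 0.715. ATF4 response genes were higher in 11 of 25 cases (16 adjusted over the list alone), with an adjusted p of 3.05e-11 but adjusted p = 0.148 with an estimated correlation. Immediate early genes were higher in 6 of 15 cases and lower in 1 (7 and 2 adjusted over the list alone), with an adjusted p of 0.000242 but adjusted p = 0.106 with an estimated correlation. Cholesterol synthesis genes were higher in 5 of 17 cases (6 adjusted over the list alone), with an adjusted p of 0.00146 but adjusted p = 0.293 with an estimated correlation. G2/M genes were lower in 12 of 22 cases (13 adjusted over the list alone), with a median of -0.42 and an adjusted p of 2.53e-09, but adjusted p = 0.0516 with an estimated correlation. Another 2 lists passed only in part of the settings, with adjusted p of 0.21 and 0.322 with an estimated correlation. In all, 1059 genes were called, 403 higher and 656 lower. The count was 634 without 60 µM 6 h replicate 3 and 604 without 20 µM 6 h replicate 1. With arrays centred 1183 were called, 216 of them higher, and the median of all genes moved from 0.03 to -0.09.

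Genes called at 20 µM and at 60 µM at 6 h were largely shared: 113 of the 158 higher and 24 of the 37 lower genes at 20 µM were also called at 60 µM, where independent sets give 9.28 and 2.2. Part of the excess may come from the shared vehicle arrays. In simulations that shared the vehicle arrays without any effect, 0 and 0.01 genes were called in both on average. Without an effect hardly any gene can be called at either dose, so these overlaps do not measure the size of that part. Folds of the doses correlated across genes at r = 0.458 (covariance 0.0558), against 0.5 (covariance 0.0337) in those simulations, and genes are not independent replicates. Between the times, 306 higher and 159 lower genes were called at 60 µM both at 6 h and at 24 h, where independent sets give 42.1 and 48.78, and 32 were called in opposite directions. Of genes called both at 60 µM and 24 h and between the vehicle times, 23 were higher in both, 22 lower in both and 221 opposite. Shared vehicle arrays alone pull these folds apart (covariance -0.0438, against -0.0338 simulated without any effect). How far the vehicle's own change enters the calls at 24 h was not tested.

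At 24 h the lower doses left few called genes. At 5 µM limma called 0 genes, with 361 at an unadjusted p under 0.05 where chance gives 713, and 1 gene without vehicle 24 h replicate 1. As at 6 h, errors that include the spread between replicate numbers can lower such counts. At 20 µM the only gene called was NQO1, the quinone reductase of the NRF2 response, 1.85-fold higher (log2 0.88 ± 0.14, adjusted p = 0.0308, n = 3), with 644 genes at an unadjusted p under 0.05. NQO1 lost its call without 20 µM 24 h replicates 2 (adjusted p = 0.165) and 3 (0.229) and without vehicle 24 h replicates 1, 2 and 3 (0.233, 0.193 and 0.0928), and under quantile normalization (0.0775), with 0.000585 to 0.242 over all alternatives. With the replicate number as a block 11 genes were called.

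Several lists nevertheless lay off 0 at 20 µM and 24 h. NRF2 targets lay higher in 20 of 24 members (1 called, 5 adjusted over the list alone). Their median was 0.14 and the adjusted p 1.38e-08 (0.00818 with an estimated correlation). G2/M and mitosis genes lay lower in 22 of 22 members (0 called, 1 adjusted over the list alone). Their median was -0.22 and the adjusted p 8.05e-11 (0.0381 with an estimated correlation). ATF4 response genes lay lower in 22 of 25 members (0 called, 1 adjusted over the list alone), with an adjusted p of 7.87e-07 but adjusted p = 0.299 with an estimated correlation. Their median of -0.28 was -0.16 without 20 µM 24 h replicate 3, and -0.13 and -0.48 without vehicle 24 h replicates 2 and 3. Ribosome biogenesis genes lay higher in 13 of 15 members (0 called, 0 adjusted over the list alone), with an adjusted p of 0.000834 but adjusted p = 0.0536 with an estimated correlation. Another 4 lists at 20 µM and 5 at 5 µM passed but lost the call in other settings, with adjusted p of 0.0783 to 0.322 and of 0.148 to 0.535 with an estimated correlation.

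At 60 µM and 24 h ZFAND2A again rose most, 15.6-fold (log2 3.97 ± 0.22, adjusted p = 7.64e-11, n = 3). FOS, an AP-1 subunit, was 9.65-fold higher (log2 3.27 ± 0.41), and HMOX1 7.91-fold (2.98 ± 0.24). HSPA6 and HSPH1 were 5.4-fold and 5.27-fold higher. Other genes that rose were the helix-loop-helix inhibitor ID2 (6.07-fold), the small GTP-binding protein GEM (5.66-fold) and the ubiquitin ligase NEURL3 (5.54-fold). The probe set named for the ribosomal RNA precursor RNA45SN5 read 6.68-fold higher, with a wide spread in vehicle (591.2 ± 344.2, SD, n = 3). Whether its signal measures the precursor itself was not tested. The cation channel TRPM4, MYCT1 and the cytokine TNFSF13 rose from dim signals of 29.1 ± 5.023, 55.03 ± 54.8 and 15.53 ± 6.573 in vehicle to 385.1 ± 115.1, 416.8 ± 107.8 and 193.2 ± 55.18 (SD, n = 3). The zinc finger gene ZNF584 fell to a dim 38.3 ± 16.59 from 190.7 ± 19.16. Lower were also DHRSX (3.17-fold; -1.66 ± 0.30), the antisense RNA ATP2A1-AS1 (3.16-fold; -1.66 ± 0.26), the palmitoyltransferase ZDHHC12 (2.54-fold; -1.35 ± 0.27) and C16orf74 (2.46-fold; -1.30 ± 0.22), and another 5 named by the rule lost their call in other settings. In all, 1539 genes were called, 717 higher and 822 lower. That count was 858 and 787 without 60 µM 24 h replicates 2 and 3 and 938 without vehicle 24 h replicate 1. With arrays centred 1307 were called, 356 of them higher.

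Genes of cell division fell broadly at 60 µM and 24 h. Of the G2/M and mitosis genes 21 of 22 fell (21 adjusted over the list alone). The median log2 fold was -0.72 and the adjusted p 1.76e-23 (0.00481 with an estimated correlation). TOP2A fell by 1.08 ± 0.10, CCNA2 fell by 1.05 ± 0.14, CCNB1 fell by 0.84 ± 0.11 and BUB1B, a spindle checkpoint kinase, fell by 0.73 ± 0.11. DNA replication and G1/S genes fell in 14 of 25 cases, with 11 not passing (19 adjusted over the list alone), and an adjusted p of 7.87e-14 (0.0454 with an estimated correlation). Their median was -0.54, and -0.33 without 60 µM 24 h replicate 2. CDC45 and MCM2, parts of the replicative helicase, fell by 0.85 ± 0.12 and fell by 0.65 ± 0.10, and RRM2, a ribonucleotide reductase subunit, fell by 0.68 ± 0.10.

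Heat shock genes rose in 15 of 19 cases at 60 µM and 24 h, with 4 not passing (16 adjusted over the list alone). Their median was 0.80 and the adjusted p 6.73e-19 (0.00687 with an estimated correlation). HSPH1 was higher by 2.40 ± 0.16 and BAG3, a chaperone cofactor, by 1.33 ± 0.15. Of the ER chaperones and ERAD genes 10 of 18 rose and 8 did not pass (11 rose adjusted over the list alone), among them DNAJB11 (1.19 ± 0.14), MANF (0.58 ± 0.12) and the lectin chaperone CALR (0.63 ± 0.13). Their median was 0.40 and the adjusted p 1.38e-08, but adjusted p = 0.0516 with an estimated correlation. Of the NRF2 targets 8 of 24 rose and 16 did not pass (9 rose and 1 fell adjusted over the list alone), with GCLM higher by 1.43 ± 0.17, PIR by 1.33 ± 0.19 and NQO1 by 0.91 ± 0.14. The adjusted p was 0.000306, but adjusted p = 0.0636 with an estimated correlation. The median of the list was 0.08 and turned to -0.02 with arrays centred. It was 0.18 and 0.13 without 60 µM 24 h replicates 2 and 3, and 0.13 and 0.25 without vehicle 24 h replicates 1 and 2.

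Immediate early genes rose in 5 of 15 cases at 60 µM and 24 h (6 adjusted over the list alone), among them the transcription factors KLF4 (1.40 ± 0.19) and EGR3 (1.04 ± 0.18). The list's adjusted p was 1.36e-05, but adjusted p = 0.0563 with an estimated correlation. NF-kB inflammatory targets rose in 4 of 14 cases (5 adjusted over the list alone), with an adjusted p of 0.000747 but adjusted p = 0.148 with an estimated correlation. The members that rose include TNFAIP3 (1.16 ± 0.16) and NFKBIA (1.30 ± 0.19), both known as inhibitors of NF-kB signalling, and the chemokine CXCL3 (1.16 ± 0.26). Of the p53 targets 6 of 20 rose and 1 fell (8 and 2 adjusted over the list alone). TP53I3 rose by 1.09 ± 0.12, the growth arrest gene GADD45A by 1.05 ± 0.18 and TP53INP1 by 1.22 ± 0.23. That list's adjusted p was 0.0014, but adjusted p = 0.0609 with an estimated correlation. Of the cholesterol synthesis genes 4 of 17 fell and 1 rose (8 and 1 adjusted over the list alone), with an adjusted p of 0.000847 but adjusted p = 0.273 with an estimated correlation. SQLE, the squalene epoxidase, fell by 0.42 ± 0.09, while PMVK, a mevalonate pathway kinase, rose by 0.58 ± 0.12. Oxidative phosphorylation genes fell in 4 of 20 cases (7 adjusted over the list alone). Their median was -0.17 and the adjusted p 0.000747, but adjusted p = 0.293 with an estimated correlation.

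Proteasome subunits passed at 60 µM and 24 h with 1 of 25 higher (adjusted p = 0.0257, and adjusted p = 0.494 with an estimated correlation), but not without 60 µM 24 h replicates 1 (0.0549) and 3 (0.304) or vehicle 24 h replicate 2 (0.185). Over all alternatives its adjusted p ran from 0.000555 to 0.329. The other 9 lists did not pass. ATF4 response genes rose in 5 and fell in 2 of 25 cases (adjusted p = 0.218, 0.0491 and 0.017 without vehicle 24 h replicates 1 and 2, and up to 0.62 over all alternatives). Of the metallothionein genes 1 rose and 1 fell (adjusted p = 0.214), and their mean, 0.02, differed in sign from the median of -0.15 and the test. Ribosome biogenesis genes rose in 2 and fell in 1 of 15 cases (adjusted p = 0.67), with a median of -0.01 against a mean of 0.08 and a test above 0. Aldehyde metabolism (1 rose and 2 fell, adjusted p = 0.284), hypoxia and glycolysis (1 rose and 1 fell, 0.843), interferon response (1 rose, 0.387), apoptosis regulators (2 rose and 1 fell, 0.564), colon epithelium markers (1 rose, 0.411) and markers of other cell types (0 called, 0.984) made up the rest. Single members that rose were ADM (2.03 ± 0.17) and MX1, an interferon-induced GTPase (1.04 ± 0.15).

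Against 20 µM at 24 h, 60 µM gave a 12.4-fold higher level of ZFAND2A (log2 3.63 ± 0.22, n = 3). FOS was 12.2-fold higher, NEURL3 6.89-fold, ID2 5.94-fold and the RNA45SN5 signal 5.90-fold, while ATP2A1-AS1 was 3.10-fold lower. Heat shock genes were higher in 14 of 19 cases (15 adjusted over the list alone), with an adjusted p of 4.3e-17 (0.00818 with an estimated correlation). Immediate early genes were higher in 8 of 15 cases (9 adjusted over the list alone), with an adjusted p of 2.07e-08 (0.019 with an estimated correlation). G2/M genes were lower in 12 of 22 cases (15 adjusted over the list alone), with an adjusted p of 3.2e-14 (0.0176 with an estimated correlation). DNA replication genes were lower in 16 of 25 cases (20 lower and 1 higher adjusted over the list alone), with an adjusted p of 1.44e-15 (0.0362 with an estimated correlation). ER chaperones (9 of 18 higher, 11 adjusted over the list alone), NF-kB targets (5 of 14, and 6) and ATF4 response genes (9 of 25, and 10) passed with adjusted p of 8.78e-08, 4.58e-06 and 0.000195, but with an estimated correlation adjusted p = 0.0609, 0.0516 and 0.452. Cholesterol synthesis (4 of 17 lower and 1 higher, 6 and 1 adjusted over the list alone) and oxidative phosphorylation (3 of 20 lower, and 8) passed with adjusted p of 0.00284 and 4.15e-05, but with an estimated correlation adjusted p = 0.308 and 0.2. In all, 1326 genes were called, 586 higher and 740 lower. The count was 641 and 674 without 60 µM 24 h replicates 2 and 3 and 704 without 20 µM 24 h replicate 1. With arrays centred 2195 were called, 261 of them higher, and the median of all genes moved from 0.04 to -0.15.

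Whether the response to 20 µM differed between the times was tested as an interaction, where a negative value means a lower fold at 24 h than at 6 h. Of 7 genes called 6 were lower: SLC7A11 by a log2 of -3.13 ± 0.49, CCN2 of -2.38 ± 0.39, HMOX1 of -2.08 ± 0.35, MBNL2, a splicing regulator, of -1.47 ± 0.25 and SLC16A14 of -0.97 ± 0.16, each with an adjusted p of 0.0151. The last was PNPLA8, a phospholipase named after its values were seen (-0.92 ± 0.17, adjusted p = 0.0335). C3orf52 alone was higher (1.27 ± 0.22). Folds of the NRF2 targets were lower at 24 h as a list, with 2 of 24 called (5 lower and 1 higher adjusted over the list alone) and an adjusted p of 5.63e-05 (0.0454 with an estimated correlation). Those of the ATF4 response were lower too, with 1 of 25 called (4 adjusted over the list alone) and an adjusted p of 3.84e-07, but adjusted p = 0.293 with an estimated correlation. Cholesterol synthesis followed with 0 of 17 called (1 adjusted over the list alone) and an adjusted p of 0.000949, but adjusted p = 0.277 with an estimated correlation. Ribosome biogenesis genes had higher folds at 24 h, with 0 of 15 called (4 adjusted over the list alone), a median of 0.43 and an adjusted p of 1.55e-08 (0.00563 with an estimated correlation). Another 3 lists passed but not in every setting, with adjusted p of 0.117 to 0.563 with an estimated correlation. The count rests on few arrays: it was 0 without 20 µM 6 h replicate 3, 18 and 3 without 20 µM 24 h replicates 1 and 3, 4 and 2 without vehicle 24 h replicates 1 and 3, and 4 and 3 without vehicle 6 h replicates 1 and 3. Without 20 µM 6 h replicate 3 none of the 6 genes kept its call (adjusted p = 0.059 for SLC7A11, CCN2, HMOX1 and SLC16A14, and 0.0744 for MBNL2 and C3orf52). Without 20 µM 24 h replicate 3 CCN2 (0.0591), C3orf52 (0.0591) and MBNL2 (0.0827) lost it, and MBNL2 also without 20 µM 24 h replicate 2 (0.0563) and 20 µM 6 h replicate 1 (0.0577). Without vehicle 24 h replicate 3 the call was lost by HMOX1 (0.0623) and by C3orf52, MBNL2 and SLC16A14 (0.0591 each), and without vehicle 24 h replicate 1 by C3orf52 (0.0555) and MBNL2 (0.0648). Without vehicle 6 h replicate 1 HMOX1 and C3orf52 lost it (0.0567 each), without vehicle 6 h replicate 2 MBNL2 (0.0758), and without vehicle 6 h replicate 3 C3orf52 (0.0552), MBNL2 and SLC16A14 (0.0578 each). Over all alternatives the highest adjusted p was 0.059 for SLC7A11, 0.0653 for CCN2, 0.0716 for HMOX1, 0.208 for MBNL2, 0.0773 for SLC16A14 and 0.0744 for C3orf52.

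For 60 µM the response differed between the times in 546 genes, with 285 folds higher and 261 lower at 24 h. The fold of RRS1 was higher at 24 h by a log2 of 2.02 ± 0.19 (adjusted p = 4.75e-06, n = 3): its intensity fell from 4790 to 2061 in vehicle and rose from 1572 to 2748 at 60 µM. RASSF1, a tumour suppressor of the RAS association family, was higher by 2.13 ± 0.47. Lower at 24 h were SLC7A11 (-2.36 ± 0.49), the synaptic vesicle gene SYNPR (-2.29 ± 0.45) and the pluripotency factor NANOG (-2.25 ± 0.52), the last a dim signal of 126.2 ± 5.951 in vehicle and 43.93 ± 12.67 at 60 µM at 24 h (SD, n = 3), whose value depends on the pseudocount (-2.65 with 1 and -1.56 with 64). Another 3 higher and 2 lower genes named by the rule lost their call in other settings.

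Cholesterol synthesis genes shifted between the times at 60 µM: 7 of 17 had a lower fold at 24 h and 10 did not pass (11 lower adjusted over the list alone). The median was -0.51 and the adjusted p 9.05e-13 (0.019 with an estimated correlation). INSIG1 was lower by a log2 of -1.99 ± 0.21, HMGCS1 of -1.44 ± 0.24 and MSMO1 of -1.31 ± 0.18. ATF4 response genes were lower in 8 of 25 cases and higher in 1 (14 and 1 adjusted over the list alone), among them SESN2 (-1.89 ± 0.35) and PHGDH, the first enzyme of serine synthesis (-1.02 ± 0.23). Their median was -0.68 and the adjusted p 2.85e-09, but adjusted p = 0.215 with an estimated correlation. Ribosome biogenesis genes had higher folds at 24 h in 5 of 15 cases and a lower one in 1 (7 and 1 adjusted over the list alone), among the higher RRP12 (1.81 ± 0.28) and POLR1B (0.85 ± 0.16). Their median was 0.50 and the adjusted p 6.74e-06 (0.0153 with an estimated correlation). NF-kB targets had higher folds in 3 of 14 cases (7 adjusted over the list alone), among them TNFAIP3 (1.39 ± 0.23) and NFKBIA (1.61 ± 0.27), and an adjusted p of 1.11e-06 (0.0436 with an estimated correlation).

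Genes of cell division and respiration had lower folds at 24 h than at 6 h at 60 µM as lists. Of the G2/M genes 1 of 22 was called (6 adjusted over the list alone), with an adjusted p of 0.000985 but adjusted p = 0.297 with an estimated correlation. Of the DNA replication genes 4 of 25 were called (7 adjusted over the list alone), such as CDC45 (-0.85 ± 0.17). That list's adjusted p was 1.8e-05, but adjusted p = 0.266 with an estimated correlation. Of the oxidative phosphorylation genes 3 of 20 were called (11 adjusted over the list alone) and 20 of 20 lay below 0, with an adjusted p of 4.76e-08 but adjusted p = 0.0776 with an estimated correlation. NRF2 targets passed too, with 2 of 24 lower (3 adjusted over the list alone) and an adjusted p of 0.0245, 0.103 without 60 µM 24 h replicate 2 and 0.00261 to 0.289 over all alternatives. With an estimated correlation adjusted p = 0.266 for that list. Heat shock genes did not pass (adjusted p = 0.502, 0.023 without 60 µM 24 h replicate 3 and up to 0.983 over all alternatives), and their median of 0.06 differed in sign from the mean of -0.17 and the test. Aldehyde metabolism genes did not pass either (adjusted p = 0.0738, 0.0343 with the replicate number as a block and up to 0.289 over all alternatives). In all, the count of 546 was 349 and 345 without 60 µM 24 h replicates 2 and 3, 331 without vehicle 24 h replicate 1 and 339 without vehicle 6 h replicate 1, 1134 with the replicate number as a block, and 234, of which 149 higher, with arrays centred.

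**Figure D4:**
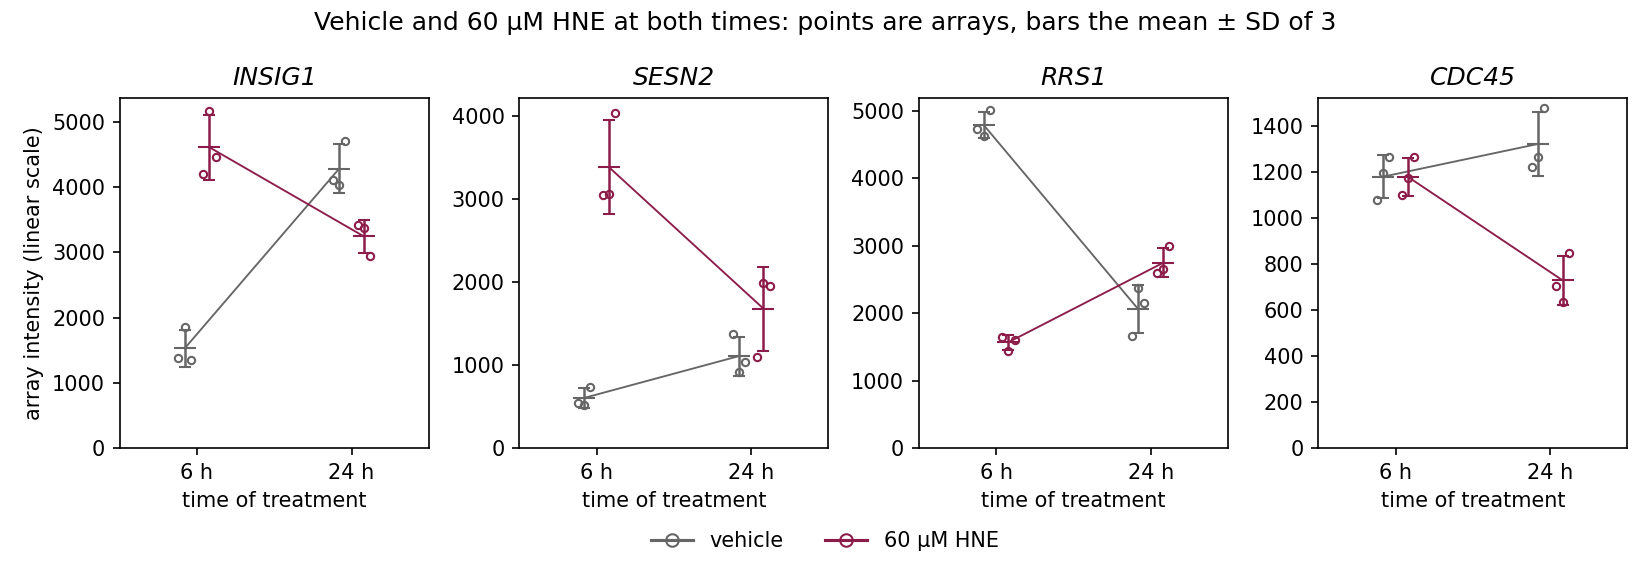
Intensity (linear, arbitrary units) of INSIG1, SESN2, RRS1 and CDC45 at 6 h and 24 h in vehicle and at 60 µM HNE, where points are arrays and bars the mean ± SD of 3. INSIG1 averaged 1528 and 4280 in vehicle but 4606 and 3242 at 60 µM, while CDC45 averaged 1181 and 1323 in vehicle and 1180 and 730.5 at 60 µM.

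Vehicle-treated cells also differed between 6 h and 24 h. TMEM201, a protein of the inner nuclear membrane, was 5.94-fold lower at 24 h (log2 -2.57 ± 0.31, adjusted p = 2.45e-05, n = 3) and ULBP3, a ligand of the receptor NKG2D, fell from 251.1 ± 16.18 to a dim 41.97 ± 18.97 (SD, n = 3). CTH, which makes cysteine from cystathionine, was 4.55-fold higher (log2 2.18 ± 0.41), PALM3 3.70-fold and CHAC1, which degrades glutathione, 3.52-fold. The lipoxygenase ALOX12B rose from a dim 43.67 ± 7.875 to 226.3 ± 85.39. Another 1 higher and 3 lower genes named by the rule lost their call in other settings. Cholesterol synthesis genes rose in 8 of 17 cases (12 adjusted over the list alone), with INSIG1 higher by 1.49 ± 0.15 and HMGCS1 by 1.25 ± 0.17. Their median was 0.43 and the adjusted p 1.98e-10 (0.0362 with an estimated correlation). Ribosome biogenesis genes fell in 10 of 15 cases (10 adjusted over the list alone), among them RRP12 (-1.53 ± 0.19) and RRS1 (-1.22 ± 0.14). Their median was -0.58 and the adjusted p 4.19e-12 (0.00174 with an estimated correlation). ATF4 response genes rose in 10 of 25 cases and fell in 1 (13 and 1 adjusted over the list alone). Their median was 0.50 and the adjusted p 1.73e-05, but adjusted p = 0.36 with an estimated correlation. Heat shock genes fell in 6 of 19 cases (7 adjusted over the list alone), such as HSPH1 (-0.86 ± 0.16), with an adjusted p of 0.000127 but adjusted p = 0.215 with an estimated correlation. Another 3 lists passed but not in every setting, with adjusted p of 0.145 to 0.468 with an estimated correlation. With the replicate number as a block proteasome subunits (adjusted p = 0.0376, with 0.0079 to 0.396 over all alternatives) and aldehyde metabolism (0.0416, with 0.0333 to 0.233) passed too. In all, 1152 genes were called, 616 higher and 536 lower, with 1914 when the replicate number was a block, 602 and 685 without vehicle 24 h replicates 1 and 2 and 706 without vehicle 6 h replicate 1. With arrays centred 855 were called, 204 of them higher, and the median of all genes moved from 0.07 to -0.04.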

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

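The tests of array scaling and of all 42 measured members for cholesterol and ATF4 genes, all tests for cell division genes and the counts of interaction splits that part all pairs or have the dose's and the time's own effects taken out were chosen only after the result was seen. The comparisons with other splits of the arrays, the other tests below and the interactions themselves were chosen before.

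At 60 µM genes of cholesterol synthesis and of the ATF4 response had higher folds against vehicle at 6 h than at 24 h, which the interaction test picked out as a difference between the times, though for the ATF4 list adjusted p = 0.215 with an estimated correlation. In the 16 called members, 15 of them with a lower fold at 24 h, 60 µM minus vehicle averaged a log2 of 1.095 ± 0.121 at 6 h and -0.181 ± 0.121 at 24 h. Vehicle arrays that were off at 1 time cannot account for the whole difference, since with the 5 µM arrays in their place it was -1.033 ± 0.171 against -1.276 ± 0.171, and in all 42 measured members, not chosen by their calls, -0.565 ± 0.145 against -0.767 ± 0.145. Array scaling as the whole cause is argued against too, since under the other scalings the higher of the list medians was -0.499. A change of the culture over time with no response left at 24 h and a response that itself declined cannot be told apart: the called members moved by 0.819 ± 0.121 in vehicle and -0.457 ± 0.121 at 60 µM, a fall that just passes the bound set beforehand (by -0.253 ± 0.125), but they had been picked by this very difference, and all 42 members were not clearly past it (by -0.072 ± 0.105).

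Genes of cell division were lower at 60 µM and 24 h, with medians of -0.722 for G2/M and -0.537 for DNA replication. Replicate 2 at 60 µM and 24 h, the array least like the others, is not the whole cause, since without it the higher of the 2 list medians was -0.327. Neither is array scaling, since relative to the median of all genes the G2/M median lay at -0.699 or lower and the DNA replication median at -0.485 or lower under the other scalings, nor RNA quality as measured by the 3′ to 5′ differences, with which as covariates they were -0.728 and -0.5. A biological response of dividing cells to 60 µM HNE remains a hypothesis, found on the same data and not itself tested. Whether fewer cells were dividing or dividing cells held less of these RNAs was not tested.

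From 20 to 60 µM at 6 h the NRF2 targets showed no further rise as a list while heat shock genes rose. Array scaling would shift both lists alike, so it cannot account for the 0.977 ± 0.075 by which the heat shock list moved more than the NRF2 list. That difference does not tell whether scaling hid a rise of the NRF2 list itself, whose mean change was 0.033 ± 0.091. Under the other scalings the median of the NRF2 list, given above, lay below 0, so they uncovered no rise. Probe sets near the top of the scanner range could hide a further rise. In the 3 risen NRF2 members under an intensity of 4000 the change was 0.037 ± 0.183, and in all 9 risen members 0.061 ± 0.12, which leaves this open because 3 genes cannot exclude a rise of 0.3. The brightest risen member, at 18131, was passed by 91 other tested genes, and each 60 µM array at 6 h held a probe set of 33477.1 or more.

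At 20 µM the folds differed between 6 and 24 h by the interaction test in 7 genes: C3orf52 (1.271), SLC7A11 (-3.134), CCN2 (-2.377), HMOX1 (-2.075), MBNL2 (-1.467), SLC16A14 (-0.972) and PNPLA8 (-0.92), with 0 genes called without 20 µM 6 h replicate 3. Lists that differed by the same test were NRF2 targets (-0.239, and -0.156 without vehicle 6 h replicate 2), ribosome biogenesis (0.425) and cholesterol synthesis (-0.209, but adjusted p = 0.277 with an estimated correlation). The ATF4 response list differed by -0.372 (but adjusted p = 0.293 with an estimated correlation), and by -0.231 without 20 µM 24 h replicate 3, -0.223 without vehicle 24 h replicate 2 and -0.607 without vehicle 24 h replicate 3. The G2/M list differed by -0.102 (adjusted p = 0.517 with an estimated correlation, -0.169 and -0.192 without vehicle 24 h replicate 2 and vehicle 6 h replicate 1). It lost its call without 20 µM 24 h replicates 2 and 3 (adjusted p = 0.0924 and 0.162), vehicle 24 h replicate 1 (0.277), 20 µM 6 h replicate 1 (0.133) or vehicle 6 h replicates 2 and 3 (0.174 and 0.0819), with 0.00189 to 0.277 over all alternatives. DNA replication genes differed by 0.132 (adjusted p = 0.563 with an estimated correlation) and lost the call without 20 µM 24 h replicate 1 (adjusted p = 0.372), vehicle 24 h replicate 2 (0.2), 20 µM 6 h replicate 1 (0.0727) or vehicle 6 h replicate 3 (0.071), with 0.00468 to 0.905 over all alternatives. Hypoxia genes differed by -0.119 (adjusted p = 0.117 with an estimated correlation, -0.183 without vehicle 24 h replicate 3) and lost the call without 20 µM 24 h replicate 3 (adjusted p = 0.0887), vehicle 24 h replicate 1 (0.0651), 20 µM 6 h replicate 2 (0.118) or vehicle 6 h replicates 2 and 3 (0.0506 and 0.0731), with 0.0134 to 0.118 over all alternatives. Chance is not excluded for the count of 7 by the test set beforehand: with time labels exchanged within the dose and within the vehicle, 9 of 100 drawn splits, the real one included, called as many genes. Of the 8 others 6 have 2 or more vehicle arrays exchanged, which brings the vehicle's own change between the times into the difference. The highest other split drawn called 175, with 2 dose arrays of each time exchanged, and a split not drawn, with all 3 vehicle arrays exchanged, called 1907. These point to a structure of the samples, the change between the times, so the 9 are no clean measure of chance. With the dose's and the time's own effects taken out, 1 of 100 arrangements of the 12 arrays, the real one, called as many, and the highest other called 1. When only arrays of equal replicate number changed places, 4 of 100 called as many and the highest other 44. These shares are under 0.05, but the tests differ, and chance is left open.

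At 60 µM the folds differed between the times in 546 genes by the same test. Those named by the rule are TNFSF13 (2.835), ZNF574 (2.371), RASSF1 (2.126), ELAPOR1 (2.106), RRS1 (2.024), CTH (-2.403), SLC7A11 (-2.356), SYNPR (-2.29), ESS2 (-2.262) and NANOG (-2.253). TNFSF13 and NANOG were dim, with group means down to 15.53 and 43.93, and their values depend on the pseudocount: 3.735 and -2.647 with 1, and 1.769 and -1.561 with 64. CTH lost its call without vehicle 24 h replicates 1 and 2 (adjusted p = 0.0562 and 0.0632) or vehicle 6 h replicate 1 (0.0591), with 0.000401 to 0.0632 over all alternatives. ELAPOR1 lost it without 60 µM 24 h replicates 2 and 3 (0.0701 and 0.0541), vehicle 24 h replicate 2 (0.052), 60 µM 6 h replicate 1 (0.0691) or vehicle 6 h replicate 1 (0.0689), with adjusted p of 0.0146 to 0.0701 over all alternatives. TNFSF13 lost it without 60 µM 24 h replicate 2 (0.0588), vehicle 24 h replicate 1 (0.0663), 60 µM 6 h replicates 1 and 2 (0.0503 and 0.0528) or vehicle 6 h replicate 1 (0.0805), with adjusted p of 0.0142 to 0.0805. ZNF574 lost it without 60 µM 24 h replicate 3 (0.0986), vehicle 24 h replicate 3 (0.0918), 60 µM 6 h replicates 2 and 3 (0.09 and 0.082) or vehicle 6 h replicates 1 and 3 (0.0622 and 0.0804), with adjusted p of 0.0078 to 0.0986. ESS2 kept its call only without 60 µM 24 h replicate 1 or vehicle 6 h replicate 1, with adjusted p of 0.0554 to 0.121 without any other of the 12 arrays: 0.121 and 0.0747 without 60 µM 24 h replicates 2 and 3, 0.0877, 0.0842 and 0.0575 without vehicle 24 h replicates 1, 2 and 3, 0.0874, 0.0742 and 0.0554 without 60 µM 6 h replicates 1, 2 and 3, and 0.097 and 0.0959 without vehicle 6 h replicates 2 and 3.

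Lists whose folds at 60 µM differed between the times by that test were cholesterol synthesis (-0.507), NF-kB targets (0.546) and ribosome biogenesis (0.496). Another 5 passed but lost the call with an estimated correlation: the ATF4 response (-0.683, adjusted p = 0.215 with an estimated correlation), G2/M (-0.25, 0.297), oxidative phosphorylation (-0.336, 0.0776), DNA replication (-0.298, 0.266) and NRF2 targets (-0.197, 0.266). Without 60 µM 24 h replicate 1 DNA replication differed by -0.465, and NRF2 targets lost the call in other settings too (adjusted p = 0.103 without 60 µM 24 h replicate 2, with 0.00261 to 0.289 over all alternatives). For the count of 546, 3 of 100 drawn splits, the real one included, called as many genes, a share under 0.05. Most of the drawn splits leave some pairs of replicate numbers together. The 2 others that called as many have 2 or more vehicle arrays exchanged, which brings the vehicle's own change between the times into the difference. The 3 are thus no clean measure of chance, and chance is not excluded by them. The highest other called 1506, with all 3 vehicle arrays exchanged between the times. It points to a structure of the samples, since it turns the vehicle's own change around and adds it to that of the dose. Of the 32 splits that part all pairs 2 called as many, the real one and that one, a share over 0.05, so chance is not excluded by these. The highest of those with fewer vehicle arrays exchanged called 411. With the dose's and the time's own effects taken out, 1 of 100 arrangements of the 12 arrays, the real one, called as many (highest other 256). When only arrays of equal replicate number changed places 4 of 100 did (highest other 956), a share just under 0.05. With the effects taken out the shares are under 0.05, but the tests differ, and chance is left open. With the replicate number as a block 1134 genes were called.

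Probe sets outside the gene table also differed from vehicle, a signal in data that the comparisons do not use. Of 5195 probe sets naming no gene 180 were called at 60 µM and 6 h (98 higher, 82 lower) and 89 at 24 h (56 and 33), which is 3.46% and 1.71% against 11.81% and 10.8% of genes. Of 1224 naming several genes 90 were called at 6 h (44 and 46) and 76 at 24 h (56 and 20). Probe sets naming none or several were fitted and adjusted together, apart from the genes. For each gene only the probe set with the highest mean was used. The cut-offs thus differ, and the shares cannot be compared directly with that of genes.

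The other counts of called genes compare 3 arrays with 3, and 10 splits are too few for a share under 0.05. As many genes as in the real split were called by 1 of 10 splits, the real one, in each comparison except 5 µM at 24 h, where 10 of 10 gave 0. The real count and the highest of the other splits were 3 and 0 at 5 µM and 6 h, 195 and 2 at 20 µM and 6 h, 1683 and 0 at 60 µM and 6 h, 1 and 0 at 20 µM and 24 h, and 1539 and 0 at 60 µM and 24 h. They were 1059 and 3 for 60 against 20 µM at 6 h, 1326 and 1 at 24 h, and 1152 and 1 for the vehicle times. Where the replicate numbers pair the arrays (60 µM at 6 h, each dose at 24 h and the vehicle times), 4 of the 10 splits part all 3 pairs, the real one included, and the highest other of these called 0. The other 6 part 1 pair and leave 2 together, and called at most 1, in the vehicle comparison.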

How the results depend on the processing

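The covariates for the 3′ to 5′ differences were chosen only after the result was seen, and the other alternatives before. Of 592 results for genes named by the rule or called as list members, 293 kept their direction and call in every setting that tested them. The stricter filter tested 537 of these results and the block within each time 469. Of 86 called lists 55 kept their direction and call. The estimated correlation is not among these settings, and many of the 86 did not pass with it. At 60 µM 4 of 12 called lists passed with it at 6 h, and 3 of 11 at 24 h. The replicate block ended 0 of the gene calls and 1 list call, that of the ATF4 response at 20 µM and 6 h (adjusted p = 0.0687, and 0.00443 to 0.527 over all alternatives), and changed no other call except the counts below and 10 lists that then passed. All 24 arrays had their highest mean deviation correlation with arrays of their own replicate number (0.153 on average, -0.076 with other numbers). The control probe set bioB-M also read 890.7 or more in every replicate 3 array and 873.7 or less in every other array. Arrays of equal number thus resembled each other, though the labels do not say why. The main fit has no term for the replicate number, so its standard errors include the spread between the numbers. Leaving out 1 array ended 978 calls of genes and 64 of lists, counted over all arrays left out, while 2916 and 541 were kept. This was run 6 or 12 times per result, so these totals do not compare with those of the other settings. Gene calls were lost in 134 cases with only the groups compared, 124 with arrays centred, 103 without the variance trend, 80 with the mean of probe sets, 73 with only the arrays of the same time, 50 under quantile normalization, 49 without the filter, 36 with the covariates and 2 with either pseudocount. List calls were lost in 14 cases with the mean of probe sets, 12 under quantile normalization, 10 with the stricter filter, 9 with arrays centred, 7 without the trend and 7 with the covariates. Without the filter 3 were lost, with only the groups compared 2, with a pseudocount of 64 1 and with the block within each time 1. Counts that moved by over 1.5 times follow, and the cause was not tested, except that fewer arrays (only those of the same time or the groups compared), more features tested (all probe sets apart) and the added condition of a 2-fold change are part of those settings by construction.

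At 5 µM and 6 h the count of 3 was 5 with the mean of probe sets, 6 with all probe sets, 11 and 10 with the block and the block within each time, 1 at 2-fold and 5 with the covariates. At 20 µM and 6 h the count of 195 was 95 with arrays centred, 92 with only the groups compared, 473 and 493 with the blocks and 30 at 2-fold. At 60 µM and 6 h the count of 1683 was 2645 with all probe sets and 260 at 2-fold. At 24 h, 5 µM gave 1 with all probe sets in place of 0. At 20 µM and 24 h the count of 1 was 0 under quantile normalization, without the filter, without the trend, with only the arrays of the same time, with only the groups compared and at 2-fold, 2 with arrays centred, with the stricter filter and with all probe sets, and 11 and 15 with the blocks. At 60 µM and 24 h the count of 1539 was 2337 with all probe sets, 994 with the same time, 827 with the groups compared, 2320 with the block within each time and 204 at 2-fold. For 60 against 20 µM at 6 h, 1059 was 675 with the groups compared, 1659 and 1685 with the blocks and 150 at 2-fold. For that pair at 24 h, 1326 was 2195 with arrays centred, 2092 with all probe sets, 798 with the same time, 305 with the groups compared, 2186 and 2238 with the blocks and 173 at 2-fold. The interaction of 20 µM had 4 genes in place of 7 without the trend, 50 with the block and 23 with the covariates. That of 60 µM had 234 in place of 546 with arrays centred, 1134 with the block and 154 at 2-fold. The vehicle times had 1738 in place of 1152 with all probe sets, 1914 with the block and 85 at 2-fold. Leaving out 1 array gave 1 to 2 genes at 5 µM, 85 to 148 at 20 µM and 1218 to 1382 at 60 µM at 6 h, 0 to 1, 0 to 1 and 787 to 1968 at 24 h, 604 to 884 and 641 to 1828 for 60 against 20 µM at 6 h and 24 h, 0 to 18 and 331 to 780 for the interactions of 20 and 60 µM, and 602 to 923 for the vehicle times.

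Reversed with the mean of probe sets were FKBP4 at 60 µM and 6 h (0.531 to -0.09), HSPA5 at 60 µM and 24 h (0.383 to -0.141), and TRAPPC12 at 60 µM and 24 h (-1.329 to 0.037) and against 20 µM (-1.544 to 0.04). The ATF4 list at 5 µM and 24 h turned from -0.15 to 0.017 without 5 µM 24 h replicate 3 (-0.372 to 0.017 over the arrays left out), and the test of DNA replication in the interaction of 20 µM turned lower with the covariates, with a median of 0.017. Signal over background limits what can be called: without detection calls a dim gene cannot be told from background, and 31 list genes lay below the filter. In simulated data 19.4%, 68.7% and 98.5% of genes changed by a log2 of 0.5, 1 and 2 were called at 60 µM and 6 h, and 28.4%, 61.2% and 93.9% at 24 h. Both runs used the same gene means and spread, so the times differ only by the random draw. They called 134 and 126 genes, against 1683 and 1539 in the data, where the cut-off was therefore less strict. These shares do not carry over to the data.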

Other observations

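The families below were chosen by gene name only after the data had been seen, with 60 tests (20 families in 3 comparisons). They reuse genes reported above and are no independent support. KIF11, KIF20A and KIF23 are in the G2/M list, POLR1B in ribosome biogenesis and GADD45A among the p53 targets. GADD45B and ID2 had already been named for their large rises. The tests of low doses were chosen before the result was seen.

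Histone, GADD45, ID and zinc finger genes lay higher as families at 60 µM and 24 h. Of 28 core and linker histone genes 13 rose and 1 fell, with a median log2 fold of 0.57 (0.49 under quantile normalization, 0.47 with arrays centred) and an adjusted p of 4.8e-05 (0.0314 with an estimated correlation). H2BC12, a histone H2B gene, averaged 4706 against 1778 in vehicle. All 3 GADD45 genes, known as stress sensors, rose with a median of 1.96 and an adjusted p of 2.5e-05 (0.0113 with an estimated correlation). At 6 h 1 of them rose and the family also passed, with a median of 1.28 and an adjusted p of 0.00235 (0.0314 with an estimated correlation), and the difference between the times did not pass (adjusted p = 0.572). Of 4 ID genes, inhibitors of helix-loop-helix factors, 3 rose with a median of 1.31 and an adjusted p of 6.94e-05 (0.0275 with an estimated correlation). Of 380 ZNF zinc finger genes 42 rose and 4 fell, with a small median of 0.19 (0.14 and 0.09 under the other scalings) and an adjusted p of 8.28e-06 (0.0126 with an estimated correlation). The difference between the times passed for the ID (adjusted p = 0.00854), histone (0.0342) and ZNF (0.0379) genes, but adjusted p = 0.153, 0.235 and 0.19 with an estimated correlation.

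Kinesins, motor proteins of which many act in mitosis, were lower at 60 µM at both times. At 6 h 11 of 31 fell and 2 rose, with a median of -0.32 and an adjusted p of 0.00197 (0.0275 with an estimated correlation). At 24 h 10 fell and 1 rose, with a median of -0.30 and an adjusted p of 7.63e-05 (0.0113 with an estimated correlation). RNA polymerase subunits fell at 6 h in 8 of 31 cases. Only POLR2D of these is named for polymerase II, the others for polymerase I or III. The family's median was -0.14 (-0.11 under quantile normalization, -0.23 with arrays centred) and its adjusted p 0.000751 (0.0113 with an estimated correlation). Folds of these subunits were higher at 24 h than at 6 h in 3 cases (POLR1C, POLR1B and POLR3E). The family's interaction median was 0.15 and the adjusted p 0.00433 (0.0179 with an estimated correlation). Of 54 ribosomal proteins 22 rose and 1 fell at 6 h, but the median of 0.25 was 0.01 under quantile normalization and 0.15 with arrays centred, and an adjusted p of 5.48e-12 became adjusted p = 0.296 with an estimated correlation.

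Lower doses may move the genes called at 60 µM in the same direction without passing the threshold. This was tested on genes called at the other time, 1539 from 24 h and 1683 from 6 h, so that no vehicle mean served both to choose and to test them. At 20 µM the signed log2 fold averaged 0.094 at 6 h, with 62.4% of genes in the direction of 60 µM, and -0.015 at 24 h, with 44.9%. The exact one-sided permutation p over both times (400 arrangements, n = 3 per group) was 0.0425, with a mean of 0.04. This meets the bound set beforehand, a p under 0.05 and a mean above 0. It fails the correction over the 2 doses (0.085), which that bound did not include, and the mean at 24 h lay below 0. For both doses the arrangements ignore the replicate numbers, though these pair the arrays with vehicle at 24 h. At 5 µM the averages were 0.027 (55.3%) and -0.016 (44.4%), with an exact permutation p of 0.33 (0.33 adjusted). A p of 0.05 or more had been set beforehand to reject the hypothesis, but that bound was wrong: other arrangements of the 5 µM arrays averaged up to 0.028, so a shift below that would be missed. The hypothesis stays undecided for both doses.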
